A study of Mus musculus with 4 samples.

How the data were processed

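Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on mouse bone marrow derived macrophages, which are primary cells grown from marrow in medium conditioned by L929 cells. The series holds 4 samples of strain C57BL/6: 1 ChIP library for BAP1, 1 for HCF1, 1 for OGT and 1 input library of DNA that was not immunoprecipitated. BAP1 was precipitated with an anti-FLAG antibody from cells of knock-in mice whose BAP1 carries a FLAG tag. HCF1, OGT and the input came from mice with untagged BAP1. Per the labels, the cells received no further treatment, and the source field names bone marrow progenitors while the cell type field names macrophages. The cell type field was followed here. The name of the deposited BAP1 list, like those of the HCF1 and OGT lists, refers to wild-type macrophages, while the labels and the design text give the knock-in for BAP1. The labels were followed. The list itself cannot settle this, and peaks of an anti-FLAG precipitate from untagged cells would not be BAP1 sites.

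Per the labels' protocols, adaptor-ligated fragments were size-selected on a gel, amplified by PCR and sequenced on an Illumina Genome Analyzer II. Per the submitters' processing notes, the tools were GSNAP and MACS 1.4 and the genome build was mm9. Their settings are not given in the sources used here. The authors deposited 1 list of peaks for each ChIP library and each list was called on a single library. Each peak has a chromosome, a start, an end and a score. The file names pair each ChIP with an input of macrophages. No list for the input itself was analysed here.

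The score deposited by the authors is 1 number per peak, and its definition is not given in the sources used here. The lowest scores were 50.01, 50.0 and 50.0 in the BAP1, HCF1 and OGT lists. If the score is 10 times the negative log10 of the peak's p-value, as this peak caller usually writes, a score of 50 stands for a p of 1e-05. Such a score grows with the number of reads, so score levels were compared within a list, and correlations between lists used ranks. An alternative applied the same cut of 100 to all 3 lists, which kept 56.0% of BAP1, 52.0% of HCF1 and 41.4% of OGT peaks. Many peaks share a score of exactly 3100.0, and the order of peaks at that level was set by width under the naming rule. The lists give no read totals, so the depth of each library is unknown. A deeper or better enriched library gives more peaks, and the list lengths are therefore no measure of how many sites a protein occupies. Fragments were amplified by PCR and no molecular identifiers are described. The exact intervals below cover counting error only, and the block bootstrap intervals also allow for dependence between neighbouring peaks. With 1 library per target, none covers the spread between libraries.

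Deposited starts were read as counted from 0, the usual form of such files, and positions are printed counted from 1 in mm9. The gene table supplied here is for GRCm38, and 19 peaks on chromosome 1 end beyond the last gene of that chromosome in it. Coordinates were not converted between builds, so no gene was assigned to any peak and no sequence was read. Of the planned results, 4 were therefore not run: the position of peaks relative to genes, the occupancy of gene lists, the overlap of target genes, and motifs at peak centres. The gene lists and motifs fixed for them were not used. Regions are named by position.

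Peaks of 2 lists were called overlapping when they shared at least 1 bp, and the share of overlapped peaks was given with an exact Clopper-Pearson 95% interval. Neighbouring peaks are not independent, so a second 95% interval came from 1000 bootstrap draws of 1 Mb blocks, or 200 draws for the correlations of scores. Placement by chance was estimated with 1000 circular shifts of 1 list within each chromosome, between the first and last peak of any list on it. For the distances between peak centres 100 shifts were used. The 3 lists were also merged into regions, which fall into 7 combinations of proteins. Co-occurrence of BAP1 and OGT on HCF1 peaks was tested with a two-sided Fisher's exact test and an odds ratio with its 95% interval. A Mantel-Haenszel odds ratio within quintiles or deciles of the HCF1 score compared peaks of like score. These tests treat peaks as units and describe the 3 libraries. With 1 library per target they say nothing of the spread between cultures or animals.

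Rules for naming regions were fixed before the data were examined. They took the 10 highest-scoring peaks of each list and the 5 highest-scoring peaks of each list that overlapped neither other list. A further rule took the 10 promoters with peaks of all 3 proteins whose lowest within-list score percentile was highest. Promoters could not be placed without an mm9 annotation, so this rule was applied to merged regions anywhere in the genome. The alternatives set before the data were examined were peak centres within 250 bp, reciprocal overlap of at least 50%, a score of at least 100, lists of equal length, autosomes only, peaks trimmed to 200 bp, and shifts of single peaks by 10 to 100 kb. The comparison of the X chromosome with the autosomes, the stitching of HCF1 peaks at most 1 kb apart and the removal of peaks over 5 kb were added after the data were seen.

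The routines were tested on simulated data. In 10000 simulated peaks with 40% placed on HCF1 peaks and the rest kept clear of them, the recovered share was 40.0%. The same list after a circular shift had an enrichment of 1.00 over further circular shifts. A value near this is given by construction, so it checks the code and not the choice of shifts. A planted odds ratio of 3 on the HCF1 peaks was recovered as 3.02 within score quintiles, and with none planted the value was 1.00, against a crude value of 1.40. The simulated overlap rates were set by these same quintiles, so confounding by score within a quintile was not tested. All 12 overlap counts matched those of bedtools 2.31.1 exactly. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.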

Results

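Binding sites of 3 nuclear proteins were mapped by ChIP-seq in mouse bone marrow derived macrophages. BAP1 is a deubiquitinase and tumour suppressor, HCF1 is a chromatin-associated cofactor, and OGT is the enzyme that attaches O-GlcNAc to proteins. The question posed by the design is where each protein sits on the genome and which sites are shared. There was 1 library per protein, so no value below has a replicate error. Intervals are 95% intervals for counting error, and block intervals also allow for dependence between neighbouring peaks.

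The HCF1 list held 31421 peaks, the BAP1 list 17662 and the OGT list 10337. HCF1 peaks were the narrowest, with a median width of 731 bp against 912 bp for OGT and 1243 bp for BAP1. In total the peaks covered 31.3 Mb for HCF1, 26.3 Mb for BAP1 and 11.5 Mb for OGT. HCF1 peaks were also the most closely packed. Of the gaps between neighbouring HCF1 peaks on a chromosome, 23.9% were 1 kb or shorter, compared with 12.3% for OGT and 7.50% for BAP1. No list held a mitochondrial peak. The read depth behind each list is unknown, and the number of peaks depends on it.

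By an overlap of at least 1 bp, most BAP1 and OGT peaks lay on HCF1 peaks. HCF1 overlapped 13186 of the 17662 BAP1 peaks, 74.7% (interval 74.0 to 75.3%), and 8490 of the 10337 OGT peaks, 82.1% (81.4 to 82.9%). BAP1 overlapped 6852 OGT peaks, 66.3% (65.4 to 67.2%). The shares depend on peak width: with every peak trimmed to 200 bp around its centre they were 44.1%, 38.6% and 29.7%, and with centres within 250 bp of each other 50.2%, 44.5% and 34.6%. Seen from the longer lists, 47.6% of HCF1 peaks were overlapped by BAP1, 26.6% of HCF1 peaks by OGT, and 35.2% of BAP1 peaks by OGT. Circular shifts placed 2.98% of BAP1 peaks and 2.66% of OGT peaks on HCF1 peaks, and 2.01% of OGT peaks on BAP1 peaks. The observed overlaps were thus 25.1, 30.9 and 33.0 times the shifted ones, and no shift reached them, the highest giving 669, 380 and 315 overlapped peaks. Peaks moved by only 10 to 100 kb, which keeps them in the same neighbourhood, overlapped more often by chance, and the enrichments were then 7.48, 7.69 and 8.53. Neither kind of shift was matched to promoters or open chromatin. The enrichments therefore do not separate shared sites from a shared preference for such regions. The shares held on each autosome. HCF1 overlapped between 68.2% of BAP1 peaks, on chromosome 14, and 79.3%, on chromosome 19. For OGT peaks on HCF1 the autosomes ranged from 79.0% to 86.6%, and for OGT peaks on BAP1 from 61.4% to 72.4%.

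Merging the lists gave 34834 regions. All 3 proteins had a peak in 5741 of them, 16.5% (16.1 to 16.9%). This count depends on the overlap rule and the score limit, and was 2855 with centres within 250 bp, 2504 with a score of at least 100 and 2303 with peaks trimmed to 200 bp. BAP1 and HCF1 without OGT accounted for 7027 regions, and HCF1 with OGT but without BAP1 for 1764. BAP1 with OGT but without HCF1 was found in 303 regions, 0.870% (0.775 to 0.973%), the least frequent of the 7 combinations. HCF1 alone made up 14391 regions, BAP1 alone 4160 and OGT alone 1448. The regions with all 3 proteins had a median width of 2094 bp, against 531 bp for HCF1 alone, 973 bp for BAP1 alone and 624 bp for OGT alone. A merged region is at least as wide as its widest peak, so this difference arises in part from merging.

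**Figure D1:**
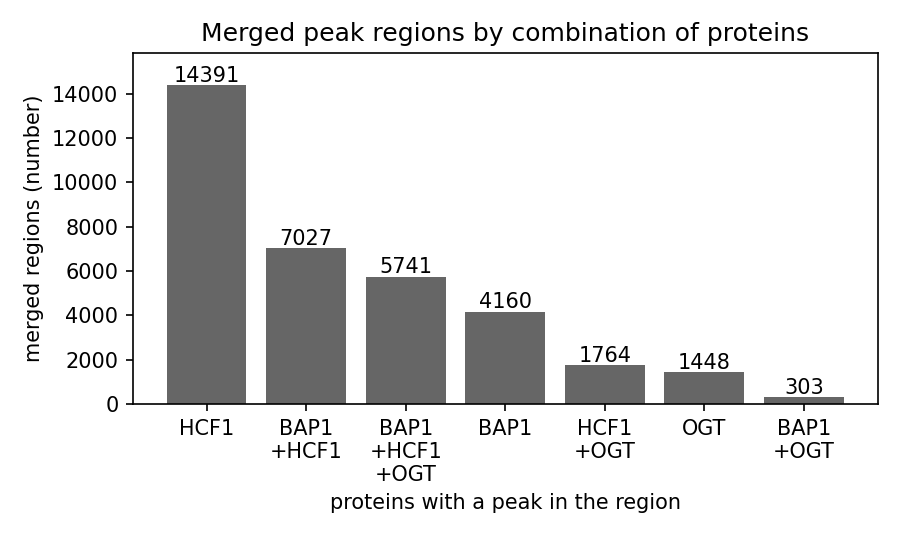
The vertical axis gives the number of merged regions and each bar stands for 1 combination of proteins with a peak in the region. By an overlap of at least 1 bp, HCF1 alone had 14391 regions, all 3 proteins 5741, and BAP1 with OGT but without HCF1 had 303.

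Overlap rose with the score of the peak in each list. In the highest decile of BAP1 scores 98.4% of peaks (97.7 to 98.9%) lay on HCF1 peaks, compared with 43.4% (41.0 to 45.7%) in the lowest decile. The share of BAP1 peaks on OGT peaks went from 13.4% in the lowest decile to 80.0% in the highest. For OGT peaks, the share on HCF1 rose from 58.3% (55.2 to 61.3%) to 96.4% (95.1 to 97.5%), and the share on BAP1 from 43.9% (40.9 to 47.0%) to 82.9% (80.4 to 85.1%). HCF1 peaks ran from 15.8% to 92.1% on BAP1 and from 4.42% to 77.0% on OGT. Between overlapping peaks, the scores of BAP1 and HCF1 had a Spearman rho of 0.39 (block interval 0.38 to 0.41). The rho was 0.24 (0.22 to 0.26) for OGT with HCF1 and 0.21 (0.19 to 0.24) for OGT with BAP1. These correlations run across peaks, which are not independent replicates. Higher-scoring peaks are also wider, and when overlap was replaced by centres within 250 bp the highest deciles fell to 54.9% for BAP1 on HCF1, 49.2% for OGT on HCF1 and 39.8% for OGT on BAP1, still above the lowest deciles at 30.2%, 31.0% and 22.4%.

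**Figure D2:**
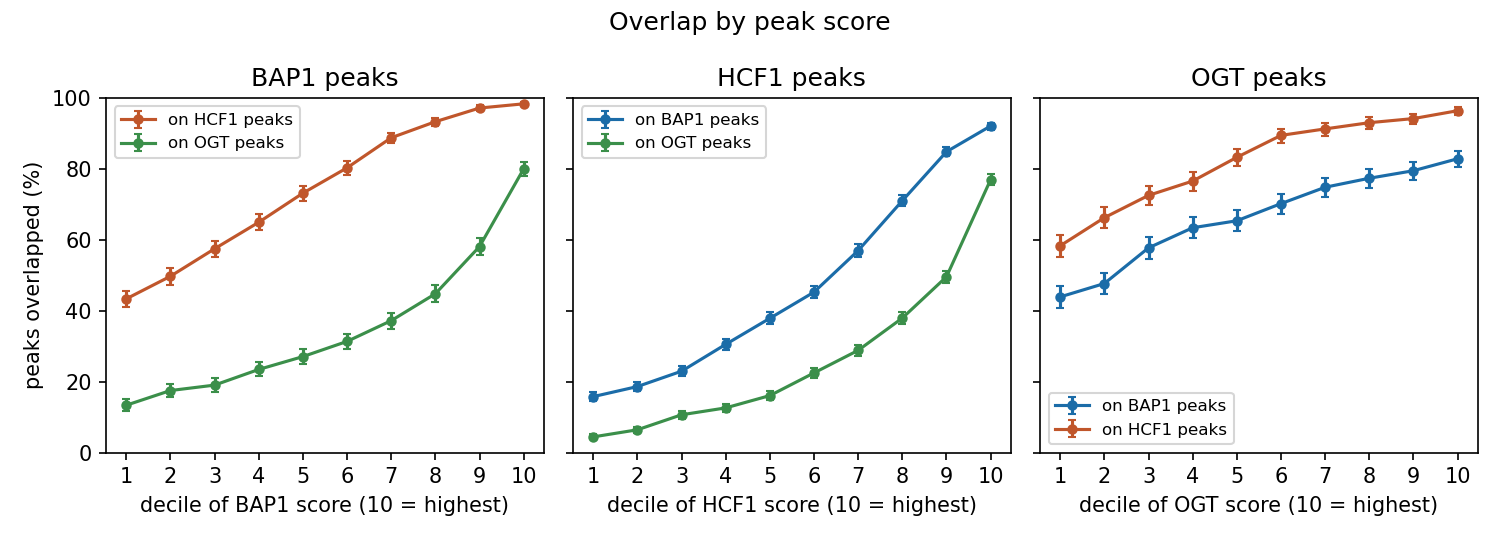
Each panel shows 1 list, with deciles of its own score on the horizontal axis and the percentage of its peaks that overlapped a peak of another list on the vertical axis. Bars are exact 95% binomial intervals, and the share of BAP1 peaks on HCF1 peaks went from 43.4% to 98.4%.

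Overlapping peaks were centred close to each other. The median distance between centres was 195 bp (190 to 199 bp) for BAP1 and HCF1, 251 bp (243 to 259 bp) for OGT and HCF1, and 241 bp (233 to 250 bp) for OGT and BAP1. Shifted peaks that happened to overlap had medians of 631, 536 and 654 bp. Centres lay within 250 bp in 49.9% of the overlapping OGT and HCF1 pairs and 51.3% of the OGT and BAP1 pairs, compared with 23.8% and 19.3% of the shifted pairs.

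BAP1 and OGT occurred together on HCF1 peaks more often than independent placement on those peaks would give. Both overlapped 6286 of the 31421 HCF1 peaks, where independence predicts 3978. OGT was present on 42.0% (41.2 to 42.8%) of the HCF1 peaks with BAP1 and on 12.6% (12.1 to 13.1%) of those without. The odds ratio was 5.04 (4.76 to 5.33, block interval 4.69 to 5.42), and the two-sided Fisher's exact p was too small for the software to represent. The size depended on the peaks and the rule used, and was 2.28 with lists of equal length, 3.02 with a score of at least 100, 3.03 with trimmed peaks and 3.18 with centres within 250 bp. Within quintiles of the HCF1 score the odds ratio fell to 2.07 (1.94 to 2.21). It was 3.42 (2.72 to 4.29) in the lowest quintile, where 12.4% of HCF1 peaks with BAP1 and 3.98% of those without had OGT. In the highest quintile these shares were 65.4% and 47.4% and the odds ratio was 2.10 (1.79 to 2.45). The quintiles in between had odds ratios of 2.75, 1.84 and 1.81, from lower to higher score. BAP1 and OGT overlapped each other less often where HCF1 was not called. OGT overlapped 44.7% (43.9 to 45.6%) of BAP1 peaks on HCF1 and 7.04% (6.31 to 7.83%) of BAP1 peaks off HCF1. Likewise BAP1 overlapped 76.0% (75.1 to 76.9%) of OGT peaks on HCF1 and 21.6% (19.7 to 23.6%) of OGT peaks off HCF1. The latter share still exceeded the 2.01% of all OGT peaks that circular shifts and the 7.77% that local shifts placed on BAP1 peaks. The 7.04% of BAP1 peaks was not set against shifts, which were not run in that direction. Within quintiles of their own scores these 2 contrasts had odds ratios of 6.04 (5.34 to 6.84) for BAP1 peaks and 9.04 (7.97 to 10.2) for OGT peaks. Peaks off HCF1 were narrower than those on it, with medians of 980 against 1389 bp for BAP1 and 649 against 1000 bp for OGT. They thus had less room to be overlapped, and these contrasts were not repeated with trimmed peaks or matched on width.

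**Figure D3:**
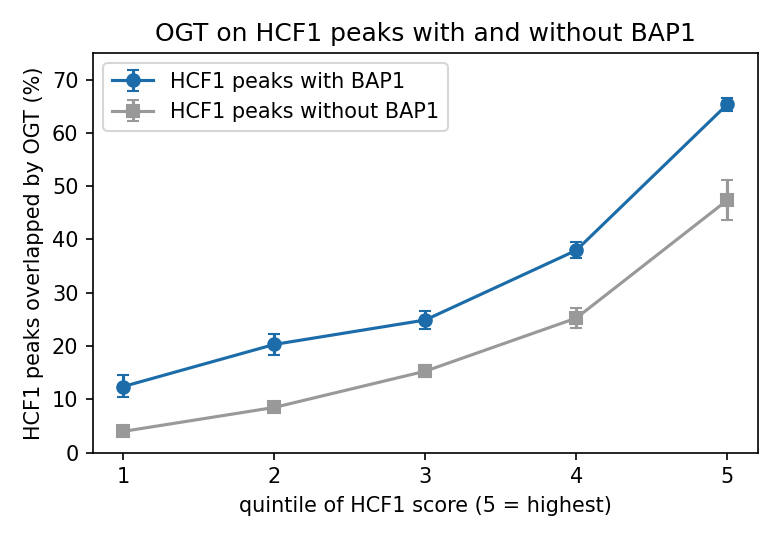
The horizontal axis gives quintiles of the HCF1 score and the vertical axis the percentage of HCF1 peaks overlapped by OGT, for HCF1 peaks with and without BAP1. Bars are exact 95% binomial intervals, and in the highest quintile the shares were 65.4% with BAP1 and 47.4% without.

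By an overlap of at least 1 bp, high-scoring sites were mostly common to the 3 proteins. The shares depend on this rule. With centres within 250 bp, the highest deciles gave 54.9% (BAP1 on HCF1), 49.2% (OGT on HCF1) and 39.8% (OGT on BAP1). The score was tied at its upper end, with exactly 3100.0 in 44 HCF1, 2 BAP1 and 1 OGT peaks and higher values in 6 HCF1 and 1 BAP1 peaks, so peaks at this level cannot be ranked reliably. Of the 50 HCF1 peaks at 3100.0 or more, 42 overlapped both BAP1 and OGT (84.0%, 70.9 to 92.8%) and 3 overlapped neither. The 10 that the naming rule took, in which wider peaks came first among ties, overlapped both. Of the 10 BAP1 peaks named, 8 overlapped both other proteins and all 10 overlapped HCF1. The BAP1 peak on chromosome 19 from 4988579 to 4989771 scored 3126.88 and overlapped HCF1 but not OGT. The same held for the BAP1 peak on chromosome 7 from 6362571 to 6363569, with a score of 3100.0. Of the 10 OGT peaks named, 9 overlapped both other proteins. The exception, on chromosome 10 from 5743719 to 5745853 with a score of 2342.67, overlapped HCF1 only. Ranked by their lowest percentile, the region with all 3 proteins that came first lay on chromosome 17 from 39979405 to 39985955, with scores of 3100.0 for BAP1, 3100.0 for HCF1 and 2819.58 for OGT. The next, on chromosome 17 from 34251041 to 34263139, spanned 12099 bp and held 2 BAP1, 4 HCF1 and 2 OGT peaks. The eighth, on chromosome 19 from 5829761 to 5852280, was the widest of these 10 at 22520 bp. The lowest percentile of any of the 10 regions in any list was 99.36. No filter for repeated or high-copy sequence was applied here. High scores in all 3 lists, as in the region that came first, may therefore reflect copy number rather than binding. Regions with all 3 proteins were unevenly spread. The 1 Mb window with the most, on chromosome 10 from 80000001 to 81000000, held 39 of them, and the window before it held 37, where the median window with any peak held 1. The window with the most was also dense in single peaks, with 80 of BAP1, 123 of HCF1 and 72 of OGT. Whether shared regions cluster beyond the density of peaks was not tested.

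By the same overlap of at least 1 bp, strong peaks of a single protein were few. The counts that follow were not repeated under another overlap rule. In the highest score decile, 26 of 1766 BAP1 peaks (1.47%, 0.964 to 2.15%), 118 of 3142 HCF1 peaks (3.76%, 3.12 to 4.48%) and 30 of 1033 OGT peaks (2.90%, 1.97 to 4.12%) overlapped neither other list. The highest such BAP1 peak, on chromosome 15 from 84659432 to 84660594, scored 1809.64 and lay 25.9 kb from the nearest HCF1 peak and 92.3 kb from the nearest OGT peak. The next scored 1520.33, on chromosome 17 from 56381089 to 56382052, 12.7 kb from HCF1 and 13.1 kb from OGT. The highest OGT peak of this kind scored 1371.96 and lay on chromosome 6 from 89017974 to 89019122. Among HCF1 peaks, the one on chromosome 15 from 35222934 to 35232839 scored 3100.0, was 9906 bp wide and lay 67.8 kb from the nearest BAP1 peak and 870.1 kb from the nearest OGT peak. The strong HCF1 peaks without the other proteins were about as wide as the shared ones, with medians of 2172 bp (quartiles 1728 and 3272 bp) and 2273 bp. Strong BAP1 peaks without the others were narrower than the shared ones, at a median of 1147 bp (quartiles 1013 and 2233 bp) against 2471 bp. So were those of OGT, at 996 bp (quartiles 792 and 1199 bp) against 1866 bp. These widths were not tested against each other.

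The lists were spread over the autosomes in similar proportions, with chromosome 11 holding 8.64% of BAP1, 8.54% of HCF1 and 9.56% of OGT peaks. The X chromosome held 233 BAP1 peaks (1.32%), 455 HCF1 peaks (1.45%) and 75 OGT peaks (0.726%). OGT overlapped 12.1% (9.24 to 15.4%) of the HCF1 peaks on X, while the autosomes ranged from 22.8% to 31.2%. Compared with autosomal HCF1 peaks in the same score decile, the odds ratio of OGT overlap on X was 0.475 (0.348 to 0.649, block interval 0.325 to 0.653). HCF1 peaks on X were narrower than autosomal ones, with medians of 516 and 735 bp, and with peaks trimmed to 200 bp the odds ratio was 0.694 (0.487 to 0.988). Single autosomes, each set against the other autosomes, ranged from 0.785 to 1.37. BAP1 overlapped 39.8% (35.3 to 44.4%) of the HCF1 peaks on X, also below its autosomal range of 42.8% to 53.0%, with a crude odds ratio of 0.724 (0.599 to 0.874). Among peaks of like score the BAP1 odds ratio on X was 0.958 (0.776 to 1.18), and no difference was then detected. For untrimmed peaks, the ratio of the BAP1 to the OGT odds ratio was 2.01 (block interval 1.26 to 3.06). This comparison was chosen after the counts per chromosome were seen. The labels do not give the sex of the mice.

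**Figure D4:**
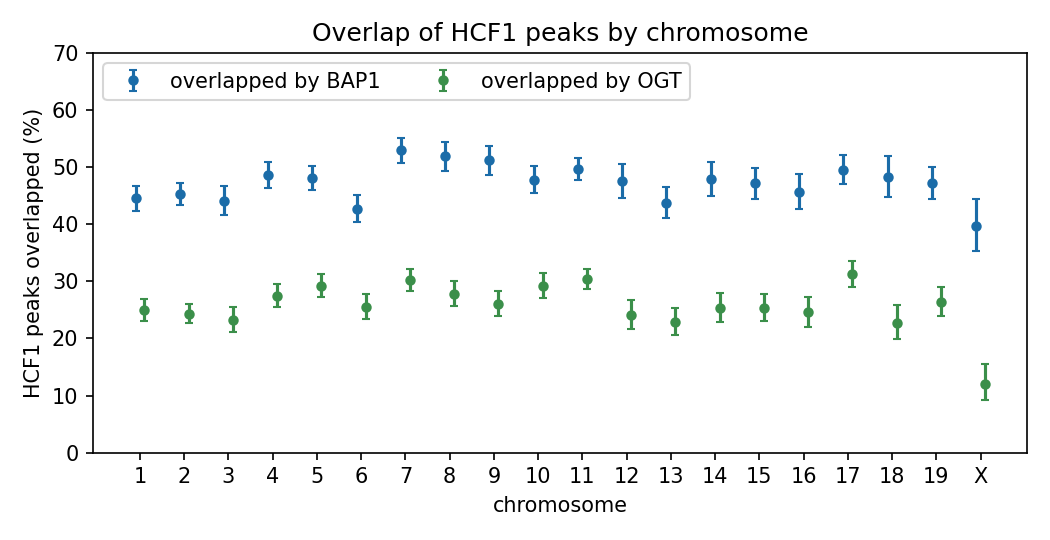
The horizontal axis lists the chromosomes and the vertical axis gives the percentage of HCF1 peaks overlapped by BAP1 or by OGT. Bars are exact 95% binomial intervals, and on the X chromosome both shares lay below their autosomal ranges, at 12.1% for OGT (autosomes 22.8% to 31.2%) and 39.8% for BAP1 (autosomes 42.8% to 53.0%).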

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

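Each pair overlapped more than shifted peaks, overlap was higher in the highest than in the lowest score decile, and the odds ratio of BAP1 and OGT on HCF1 peaks was above 1 under the alternatives run for each. The size of the overlaps depended on how overlap was defined and how long the lists were, and so did their order: OGT peaks lay on HCF1 peaks more often than BAP1 peaks did in the main comparison and with the stricter score, and less often with centres, reciprocal overlap, trimmed peaks or equal lengths. In the order BAP1 on HCF1, OGT on HCF1 and OGT on BAP1, the shares were 50.2%, 44.5% and 34.6% with centres within 250 bp, 56.9%, 53.6% and 39.1% with reciprocal overlap of 50%, and 44.1%, 38.6% and 29.7% with peaks trimmed to 200 bp. They were 80.2%, 86.7% and 65.3% with a score of at least 100, and 65.6%, 59.6% and 53.3% with lists of equal length. Smaller targets are also met less often by chance, and the enrichments over circular shifts were then larger: 73.8, 64.6 and 88.1 for centres, 82.6, 84.0 and 75.1 for reciprocal overlap, 81.4, 70.5 and 95.2 for trimmed peaks, and 37.5, 43.2 and 44.4 for the stricter score. With lists of equal length the enrichment was 42.5 for BAP1 on HCF1 and 45.9 for OGT on HCF1. With local shifts the values dropped to 7.48, 7.69 and 8.53. Regions with all 3 proteins numbered 2855 with centres, 2504 with the stricter score and 2303 with trimmed peaks, and between 3961 and 5691 with reciprocal overlap, equal lengths or autosomes only. With centres, the highest score deciles gave 54.9%, 49.2% and 39.8%, and the lowest 30.2%, 31.0% and 22.4%. With the stricter score the median centre distances were 262 bp for OGT and HCF1 and 257 bp for OGT and BAP1. Restricting to autosomes moved none of these shares or enrichments beyond their intervals. That odds ratio ran from 2.28 with equal lengths to 5.04 on autosomes. After the data were seen, HCF1 peaks were stitched over 1 kb, which gave 5.81, peaks over 5 kb were left out, which gave 5519 regions with all 3 proteins, and the odds ratio of OGT on X was recomputed, ranging from 0.407 with the stricter score to 0.694 (interval 0.487 to 0.988) with trimmed peaks. Alternatives that need genes or sequence were not run, and gaps between peaks, wide peaks and the widths of strong lone peaks had no alternative. The depth of each library is unknown, so a peak missing from a list is not shown to be an unoccupied site. No paired analysis was possible because each protein has 1 library.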

Other observations

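Wide peaks were mostly common to the 3 proteins. Of the 151 BAP1 peaks over 5 kb, all 151 overlapped at least 1 other list and 138 overlapped both (91.4%, 85.7 to 95.3%), against 32.9% of the narrower BAP1 peaks. Of the 207 HCF1 peaks over 5 kb, 160 overlapped both other lists (77.3%, 71.0 to 82.8%), against 19.6% of the narrower ones. For OGT the shares were 79.6% (65.7 to 89.8%) of 49 wide peaks and 62.3% of the others. A wide peak has more room to be overlapped, and this was not corrected for. On sequences outside the assembled chromosomes, which mm9 lists as random or unplaced, there were 39 BAP1, 52 HCF1 and 25 OGT peaks. HCF1 overlapped 51.3% (34.8 to 67.6%) of these BAP1 peaks, against 74.8% on the autosomes. The other 5 shares there were lower in 2 cases, 40.4% of HCF1 peaks on BAP1 against 47.7% and 76.0% of OGT peaks on HCF1 against 82.2%, and higher in 3, 43.6% of BAP1 peaks on OGT against 35.4%, 36.5% of HCF1 peaks on OGT against 26.8% and 68.0% of OGT peaks on BAP1 against 66.3%, and in each case the autosomal value lay within the interval.

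For the patterns that follow, 2 of the tests were chosen after the result was seen: the share of shared BAP1 peaks on HCF1, and the share of strong HCF1 peaks without the other proteins. The X chromosome was picked out after the counts per chromosome were seen.

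The first pattern is the joint occurrence of BAP1 and OGT on HCF1 peaks. If it came only from both proteins being detected at strong HCF1 sites, and the deciles captured that strength, the association should vanish within them. The odds ratio within score deciles was still 1.96 (1.83 to 2.09). Peaks within a decile differ in score, from 536.57 to 3226.07 in the highest, so a remaining effect of strength was not excluded. Matching on score lowered the odds ratio from its crude value of 5.04. Higher-scoring peaks are also wider, so the part due to score itself is not known. Allowing for the extra room that wide peaks offer did not remove the association either. The odds ratio was 2.20 (2.05 to 2.36) for peaks cut to 200 bp and compared within deciles of HCF1 width. Score and width were held fixed in separate tests. Regions that any immunoprecipitation recovers over input remain open, since no library with a control antibody or with untagged cells and anti-FLAG was analysed here. Of the BAP1 peaks shared with OGT, 94.9% also lay on HCF1. Such regions and binding of the 3 proteins at the same sites, the biological alternative, would both give a high share. The share cannot decide between them, and they were not separable.

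The second pattern is the 14394 HCF1 peaks that overlapped neither BAP1 nor OGT, 45.8% of the list. They were not mainly flanking pieces of shared peaks, because 16.3% (15.7 to 16.9%) lay within 1 kb of an HCF1 peak that overlapped BAP1 or OGT. Sites near the calling limit that the other lists missed may account for most of them: in the highest HCF1 score decile the share was 3.76% (3.12 to 4.48%), and 26.2% of these peaks scored at least 100. The limit of 5% used for this test was set after the overlap by score was seen. Weaker HCF1 sites that truly lack the other proteins would give the same shares, so this test cannot tell missed sites from empty ones. A class of HCF1 sites that truly lack the other proteins stays open, above all for the 118 in the highest decile.

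The third pattern is the low OGT overlap of HCF1 peaks on X. Weaker peaks on X, as a single copy of the chromosome would give, may lower overlap. Among peaks of like HCF1 score the odds ratio was still 0.475 (0.348 to 0.649). Matching on the HCF1 score does not equalise how readily OGT peaks are called, so weaker OGT signal on X is not excluded. The 75 OGT peaks on X had a median score of 71.48, against 86.6 on the autosomes. If the deficit were common to any second protein, BAP1 should show it as strongly, but its odds ratio was 2.01 times that of OGT (block interval 1.26 to 3.06). By an overlap of at least 1 bp, the deficit was thus larger for OGT than for BAP1. The comparison was not repeated with trimmed peaks. It also does not exclude a common loss of signal, since BAP1 was the only other protein. The OGT list was also shorter, at 10337 peaks against 17662. With BAP1 overlap held fixed as well as the HCF1 score, the odds ratio of OGT overlap on X was 0.477 (0.350 to 0.652). On BAP1 peaks within deciles of the BAP1 score it was 0.500 (0.348 to 0.719). HCF1 peaks on X were also narrower, with a median of 516 bp against 735 bp on the autosomes, and with peaks trimmed to 200 bp the odds ratio was 0.694 (0.487 to 0.988), so width may account for part of the deficit. Whether HCF1 sites on X differ in kind from autosomal ones, or whether the OGT library was less sensitive there, was not tested, and the pattern rests on 55 HCF1 peaks with OGT in 1 library.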
